A study of Homo sapiens with 2 samples.

How the data were processed

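RNA was measured by sequencing in K562, a human erythroleukemia cell line that carries the BCR-ABL1 fusion. One culture was exposed for 48 h to 1 µM cabozantinib (XL184), an inhibitor of MET, VEGF receptors, AXL and other kinases, and the other for 48 h to its solvent DMSO. Per the labels' protocols, total RNA was isolated on a column kit and libraries were built with a strand-specific TruSeq protocol. Whether poly(A) RNA was selected or ribosomal RNA removed is not given in the sources used here. Each group holds 1 library, and the group of each library was taken from its treatment label.

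The deposited count files hold whole-number counts per Entrez gene for each library. Per the file headers, reads were aligned with Rsubread to hg19, and the submitters' processing notes name hg19 and GRCh37. The table layout is the one featureCounts writes. The version, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here, so genes that overlap or share sequence with near-identical copies are uncertain. The files hold 25702 genes, of which 17392 had a count in at least 1 library. All positions are those of the deposited annotation on hg19, counted from 1.

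The authors' deposited table lists the same 17392 genes with a symbol (907 had none there), and 23696 of the gene IDs were matched to a RefSeq table of another assembly for names and gene types only. It holds posterior probabilities of equal and of differential expression, a deposited score between 0 and 1 per gene. It also holds a plain and a shrunken fold ratio as deposited. Their direction, cabozantinib over DMSO, was read from the counts of the labelled libraries, whose log2 ratio before scaling differed from the log2 of the shrunken ratio by 0.0391 to 0.0558 in the 11445 genes with at least 100 counts. Its 4 columns of values per library carry no label of a sample and were not used. The tool that made the deposited table is not given in the sources used here. Its column names are those EBSeq writes.

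The libraries were scaled with TMM factors of edgeR 4.0.16 in R 4.3.3 (1.03 for DMSO and 0.971 for cabozantinib). The log2 ratio of a gene was that of its counts plus a pseudocount of 0.5, each divided by the effective library size, cabozantinib over DMSO. Levels in CPM (counts for each 1e6 counts) were computed on the same sizes from the deposited counts. A gene was called measured at 1 CPM or more in at least 1 library. With 1 library per group no test of the conditions was possible, and no p-value was computed. A gene was called higher or lower when it differed by at least 2-fold and the exact (Clopper-Pearson) 95% interval of the ratio of its 2 counts excluded no change. Members of gene lists were called at 1.5-fold, a log2 size of 0.58, under the same condition. These intervals cover counting error only, not differences between cultures or library preparations.

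Before the data were examined, 40 gene lists with 747 entries were fixed, together with the rule for the genes named. The first part of the rule took 12 genes higher and 12 lower by the bound of the interval nearest no change, among those with a mean of at least 5 CPM. Pseudogenes, antisense RNAs, small RNAs and uncharacterised loci were left out there. This was done by taking only genes typed as protein-coding, so other long non-coding RNAs and genes without a type were left out too. The second part took up to 2 members each way per list, and the third took the globins, the kinase list, GATA1, KLF1 and MYC whatever their values. This gave 127 genes, a few of which are not reported here. Other members appear only as examples within their list. The median log2 ratio of each list was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these libraries only. Counting intervals of medians came from 1000 Poisson resamples. Shares of counts have exact 95% binomial intervals.

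The scripts were tested on simulated counts for 25702 genes with the levels and sizes of these libraries. Only Poisson counting error was simulated, without differences between cultures or library preparations, so the rates below are not those of the real calls. In that simulation of cabozantinib against DMSO, 95.3% of intervals held the simulated ratio, and 12 of 12206 measured genes with no change passed the 2-fold rule. Of genes simulated at a log2 change of 1.2, 96.0% passed, and at -1.2, 95.9%. At log2 changes of 2.4 and -2.4, 100% passed. Alternatives covered the scaling (total counts, DESeq2 1.42.0 size factors, upper quartile), the filter, the pseudocount, the size threshold, the deposited fold, a length trend and summed CPM. Alternatives on GC content (from GENCODE 29 transcripts matched by gene ID), on totals without globins and mitochondrial genes, on protein-coding genes and on abundance were added after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 was used.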

Results

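Gene expression was compared between K562 cells kept for 48 h in 1 µM cabozantinib and cells kept for 48 h in DMSO, which asks how the kinase inhibitor changes the transcriptome of this leukemic line. Each group held 1 library, so no difference below has a replicate check, and differences are described by size and counting error. The DMSO library held 25025243 counts over 16631 genes and the cabozantinib library 25505289 counts over 16243 genes. At this depth 12536 genes were measured, 11229 of them protein-coding.

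With cabozantinib, most measured members of the globin, heme synthesis and red cell membrane lists were higher by 1.5-fold, and most measured members of the amino acid stress, STAT5, NF-kB and myeloid lists were lower. By the 2-fold rule 340 genes (2.71% of those measured) were higher and 722 (5.76%) were lower. Most genes moved little, with 9841 (78.5%) within 1.5-fold. The median log2 ratio of all measured genes was 0.01.

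**Figure D1:**
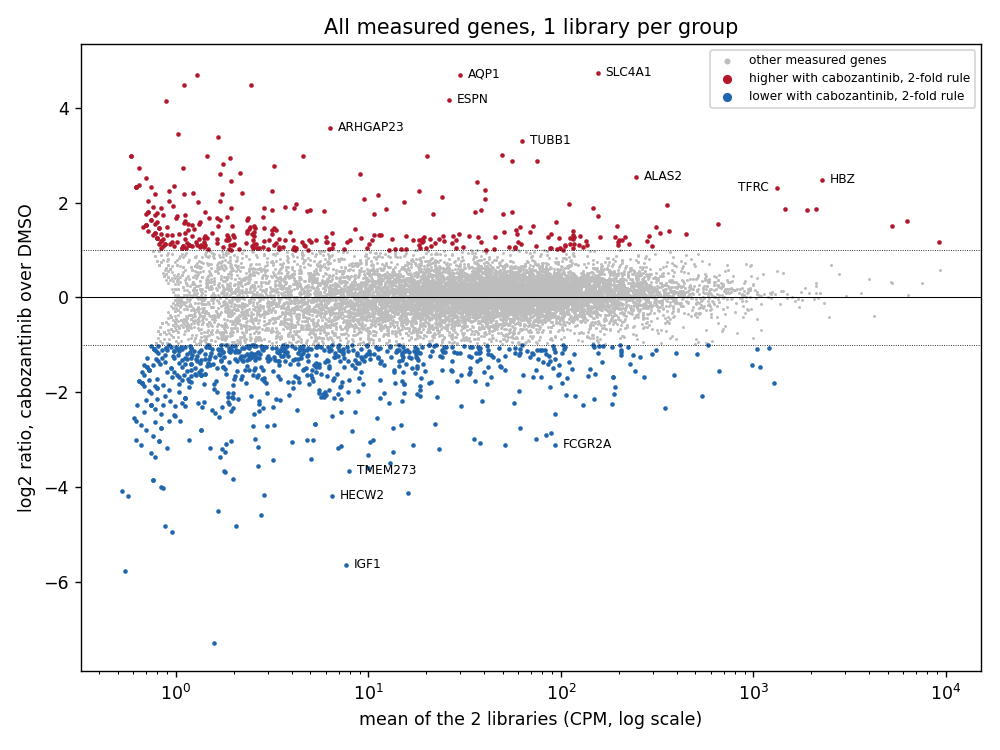
Each point is 1 measured gene, with the mean of both libraries in CPM on a log scale against the log2 ratio of cabozantinib over DMSO, and dotted lines at 2-fold. The 340 genes higher by the 2-fold rule are red and the 722 lower are blue, and some genes named in the text are labelled, from SLC4A1 at 4.74 to IGF1 at -5.64.

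SLC4A1 (Entrez 6521), the anion exchanger band 3 of the red cell membrane, was 26.7-fold higher (95% counting interval 23.8 to 30.2), from 288 to 7416 counts or 11.2 to 299 CPM. It lies on hg19 chromosome 17, 42325758 to 42345502, with 20 exons in the deposited annotation. AQP1 (Entrez 358, chromosome 7, 30951415 to 30965131), a water channel, was 25.9-fold higher (20.1 to 34.7), from 2.21 to 57.9 CPM. ESPN, an actin-bundling protein on chromosome 1 at 6484848 to 6521004, was 17.9-fold higher (14.2 to 23.2). ARHGAP23 was 11.9-fold higher (8.01 to 19.0), and TUBB1, a beta-tubulin of platelets, 9.89-fold higher (8.79 to 11.2). TNS1 (7.99-fold), EPB42 (7.93-fold), CA1 (7.40-fold), AHSP (7.34-fold), ALAS2 (5.80-fold), HBZ (5.60-fold) and TFRC (4.94-fold) completed the 12 named by this part of the rule.

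Among the lower genes, IGF1 (Entrez 3479, chromosome 12, 102789645 to 102874378), a growth factor, had 388 counts in DMSO and 7 with cabozantinib, 49.8-fold lower (25.6 to 133). HECW2, a ubiquitin ligase on chromosome 2 at 197063977 to 197457335, was 18.4-fold lower (11.5 to 33.5). IL10RA, a chain of the interleukin-10 receptor, was 11.3-fold lower (8.59 to 15.4), and CD33, a myeloid lectin, 10.1-fold lower (7.48 to 14.2). FCGR2A, an Fc receptor, was 8.72-fold lower (7.94 to 9.62), from 166 to 19.1 CPM. IL20RB was 9.21-fold lower, FN1, which encodes fibronectin, 8.70-fold, the adaptor SH3BP2 8.45-fold, and CHAC1, a glutathione-degrading enzyme of the stress response, 7.96-fold. TMEM273 (12.8-fold lower), TM6SF1 (12.2-fold lower) and CFAP161 (9.62-fold lower) were the others.

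Of 10 measured members of the globin list, which includes the alpha-globin chaperone AHSP, 9 were higher and none lower by 1.5-fold. Their median log2 ratio was 1.73 (counting interval 1.72 to 1.87), at percentile 100 of the random lists. Globins took 1.42% of all counts in DMSO (1.42% to 1.43%) and 3.85% with cabozantinib (3.84% to 3.86%). The embryonic HBZ, on chromosome 16 at 202854 to 204504, went from 686 to 3844 CPM, and the embryonic HBE1, on chromosome 11 at 5289580 to 5291373, from 2730.0 to 7792 CPM, 2.85-fold higher. The fetal HBG1 (chromosome 11, 5269502 to 5271087) was 3.06-fold higher and HBG2 (5274421 to 5276011) 2.23-fold higher. These near-identical genes share reads, and together they took 0.908% of counts in DMSO and 2.16% with cabozantinib. HBA1 and HBA2, also near-identical, were 3.62-fold and 3.66-fold higher, and their joint share went from 0.158% to 0.544%. The adult HBB had 22 counts in DMSO and 61 with cabozantinib, 2.84-fold higher (1.75 to 4.93), and HBD was 4.49-fold higher. HBQ1 differed by a log2 ratio of 0.32, inside 1.5-fold, and HBM had 0 counts in both libraries, which allows up to 3 counts in each.

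**Figure D2:**
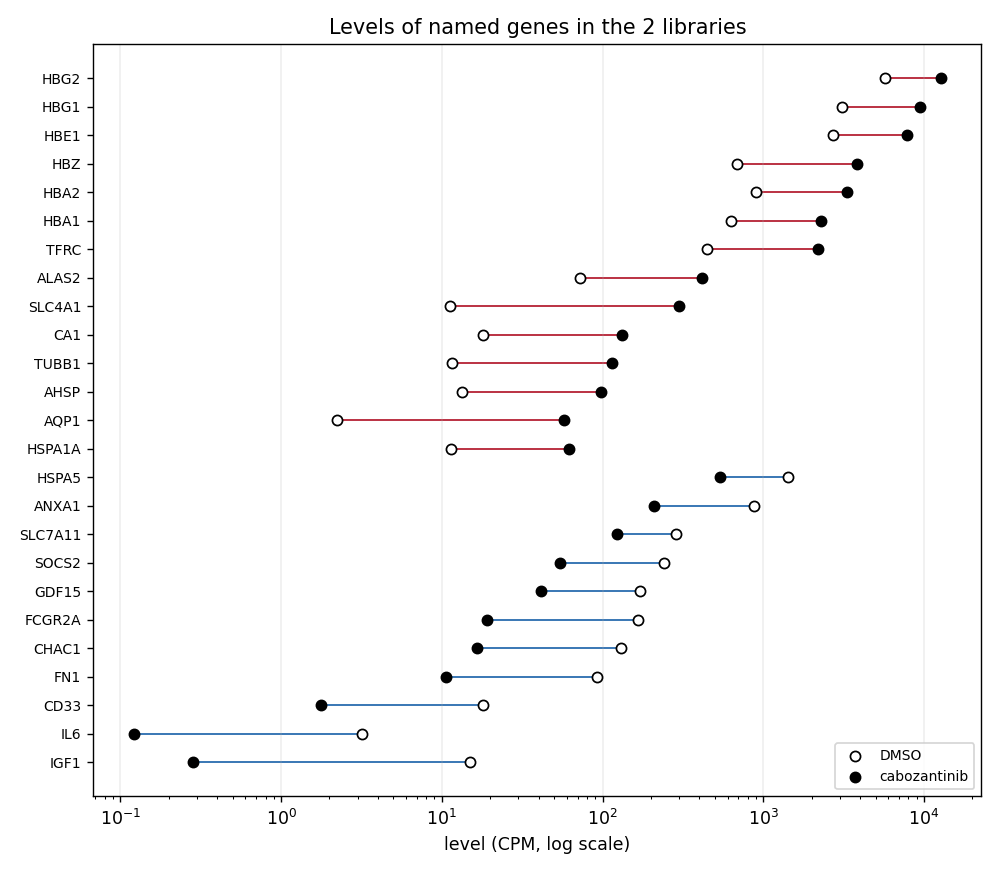
Open circles give the level in the DMSO library and filled circles the level in the cabozantinib library, in CPM on a log scale, for 25 genes named in the text, with 1 library per group. Red lines mark genes higher with cabozantinib, such as AQP1 from 2.21 to 57.9 CPM, and blue lines genes lower with it, such as CD33 from 18.1 to 1.78 CPM.

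Of 14 members of the heme biosynthesis and transport list 9 were higher and 0 lower, with a median log2 ratio of 1.2 (1.12 to 1.24) at percentile 100. ALAS2, the erythroid form of the first enzyme of the pathway, was 5.80-fold higher (5.52 to 6.10), on chromosome X at 55035488 to 55057497. SLC25A37, the mitochondrial iron importer mitoferrin, was 3.84-fold higher (3.70 to 3.98). The housekeeping form ALAS1 differed by a log2 ratio of 0.10. In the iron list 4 of 13 members were higher and 0 lower, with a median of 0.11 at percentile 67.2. TFRC, the transferrin receptor, was among them, from 447 to 2207 CPM, as was the ferrireductase STEAP3, 2.20-fold higher (2.04 to 2.37).

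Of 21 measured red cell membrane and blood group genes, 15 were higher and 0 lower. The median log2 ratio was 1.07 (1.01 to 1.21) at percentile 100, with SLC4A1 and AQP1 as the highest members. Members of sequence-sharing families, such as RHD and RHCE, are uncertain individually. Among 19 red cell enzymes and late erythroid genes, 10 were higher and 1 lower, with a median of 0.74 (0.66 to 0.79) at percentile 100. CA1, carbonic anhydrase of red cells, led this list, and TMCC2 was its lower member, 4.05-fold lower (3.02 to 5.59). Of 19 erythroid transcriptional regulators and receptor genes 10 were higher and 1 was lower, with a median of 0.62 (0.52 to 0.68) at percentile 100. EPOR, the erythropoietin receptor, was 3.40-fold higher (3.10 to 3.74), LMO2 2.64-fold higher (2.5 to 2.80), and KLF1, a master regulator of globin genes, 2.32-fold higher (2.22 to 2.42). GATA1 had a log2 ratio of 0.39 (0.34 to 0.44), short of 1.5-fold. MYB, a regulator of immature progenitors, was 1.77-fold lower (1.70 to 1.84). As the ratio of summed CPM, the regulator list gave 0.34 in place of 0.62, below the 1.5-fold size.

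Of 9 measured megakaryocyte and platelet genes 3 were higher and 2 lower, with a median log2 ratio of -0.04 at percentile 44.5 that turned to 0.20 as the ratio of summed CPM. TUBB1 and ITGB3 were higher (9.89-fold and 2.92-fold), whereas ITGA2B, the platelet integrin alpha chain, was 2.19-fold lower (1.82 to 2.67) and RUNX1 1.94-fold lower (1.81 to 2.08). Of 7 measured granulocyte and monocyte markers 0 were higher and 4 lower, with a median of -0.97 (-1.54 to -0.75) at percentile 0.14. SPI1, the myeloid regulator PU.1, was 2.99-fold lower (2.53 to 3.55), from 22.6 to 7.55 CPM. Few stem and progenitor markers were measured, and 2 of these 3 were lower, ANGPT1 1.52-fold and GFI1 2.81-fold, with a list median of -0.60 at percentile 5.13. Both measured lymphocyte markers were lower, with a median of -1.48 at percentile 4.95, CD3D going from 9.59 to 2.38 CPM. Of 4 measured fibroblast and epithelial markers 1 was lower, COL1A2 at 5.04-fold (3.01 to 9.44). That list's median was 0.04 at percentile 60.0, and it turned to -0.05 under scaling by total counts.

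Of 28 genes of the amino acid and ATF4 response 26 were lower and 0 higher, with a median log2 ratio of -1.37 (-1.43 to -1.32) at percentile 0. NUPR1 had 41 counts in DMSO and 2 with cabozantinib, 16.0-fold lower (5.12 to 168), and VLDLR was 9.22-fold lower (4.71 to 23.3). Enzymes of serine synthesis belonged to this set, with log2 ratios of -1.51 for PHGDH and -1.64 for PSAT1, and so did TRIB3 at -2.33, DDIT3 at -1.81 and ASNS, asparagine synthetase, at -1.07. ATF4 itself had a log2 ratio of -0.18. Of 16 endoplasmic reticulum chaperone genes 7 were lower and 0 higher, with a median of -0.48 (-0.59 to -0.45) at percentile 0. HSPA5, which encodes the chaperone BiP, went from 1431 to 535 CPM, 2.67-fold lower (2.62 to 2.73), and HERPUD1 was 2.64-fold lower (2.47 to 2.83).

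In the list of 12 heat shock proteins 8 were higher and 0 lower, with a median log2 ratio of 0.91 (0.88 to 0.95) at percentile 100. HSPA1A was 5.44-fold higher (4.80 to 6.19) and HSPA1B 4.84-fold higher (4.32 to 5.45), and these near-identical genes cannot be separated with certainty. HSPA8, the constitutive member, had a log2 ratio of 1.85. Of 16 p53 target genes 2 were higher and 5 lower, with a median of -0.25 at percentile 0.57. TNFRSF10B, a death receptor, was 7.47-fold lower (6.81 to 8.23) and GDF15 4.18-fold lower (3.90 to 4.48), while BTG2 was 2.52-fold higher (2.33 to 2.73) and SESN1 1.51-fold higher. K562 cells are known to lack functional p53. Among 14 NRF2 target genes 1 was higher and 6 lower (median -0.31, percentile 0.13). The cystine transporter SLC7A11, which the ATF4 list also holds, was 2.33-fold lower (2.24 to 2.43), OSGIN1 was 2.15-fold lower and GCLC 1.57-fold higher. Of 24 lysosome and autophagy genes 4 were lower and 0 higher (median -0.05, percentile 15.7), among them WIPI1, 2.39-fold lower, and MAP1LC3B, 1.95-fold lower.

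**Figure D3:**
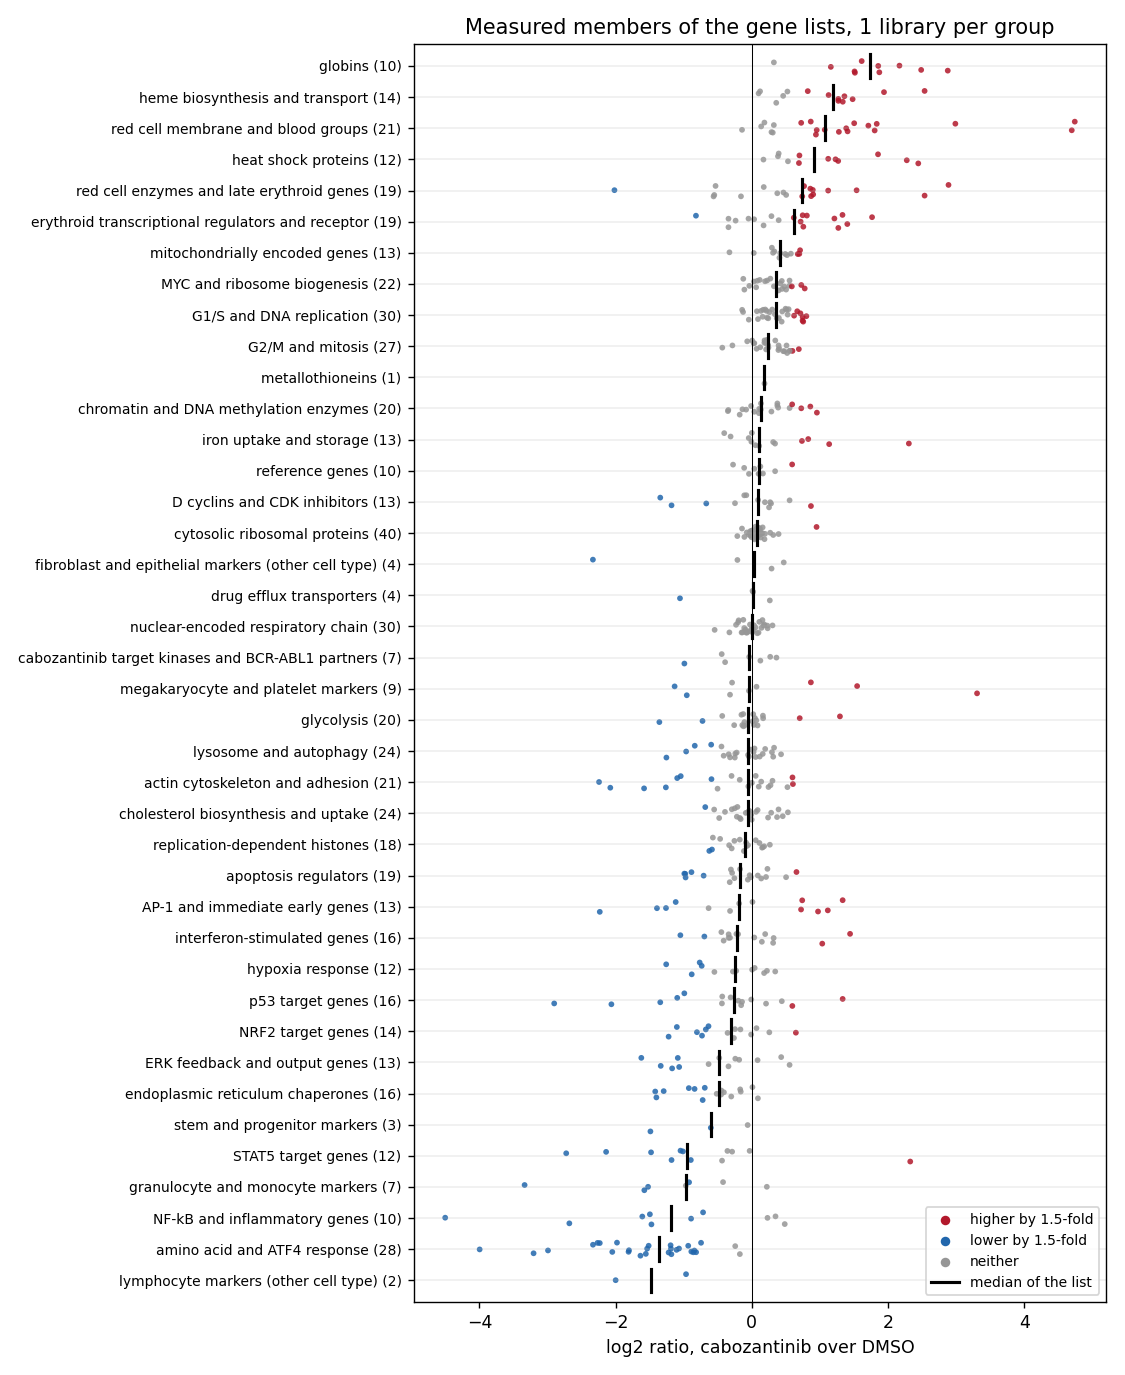
Each point is the log2 ratio of cabozantinib over DMSO of 1 measured member of a gene list, with the number of measured members in brackets and the list's median as a black bar, from 1 library per group. Red and blue points are members higher or lower by 1.5-fold whose counting interval excludes no change; list medians run from 1.73 for globins to -1.48 for the 2 measured lymphocyte markers, with -1.37 for the 28 genes of the amino acid and ATF4 response.

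Of 15 genes on the list of kinases that cabozantinib inhibits and BCR-ABL1 partners, 7 were measured. MET had 126 counts in DMSO and 89 with cabozantinib, a log2 ratio of -0.44 (-0.85 to -0.04), and AXL had 63 and 46 counts (-0.39, -0.98 to 0.17). KDR, RET, TEK, ROS1 and NTRK2 had 0 counts in both libraries, which allows up to 3 counts in each, and FLT3 had 1 and 0. FLT1 had 12 and 0 counts and KIT 17 and 18, all below 1 CPM. FLT4 was 1.99-fold lower (1.18 to 3.51) on 46 and 22 counts. TYRO3, at 54.4 and 59.3 CPM, had a log2 ratio of 0.13, and MERTK one of -0.04. ABL1 (chromosome 9, 133589268 to 133763062) and BCR (chromosome 22, 23522552 to 23660224), whose counts include reads of the fusion transcript, had log2 ratios of 0.27 (0.22 to 0.32) and 0.36 (0.29 to 0.43). Over the 7 measured members the median was -0.04 at percentile 45.2, with 0 higher and 1 lower, and it turned to 0.20 with a filter of 5 CPM and to 0.26 as the ratio of summed CPM.

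Of 12 STAT5 target genes 7 were lower and 1 higher, with a median log2 ratio of -0.95 (-1.02 to -0.85) at percentile 0. SOCS2, a feedback inhibitor of cytokine signalling, was 4.41-fold lower (4.16 to 4.68), from 241 to 54.7 CPM, and SOCS1 6.61-fold lower (4.0 to 12.3). The kinase gene PIM1 had a log2 ratio of -1.48 and CISH one of -1.01. OSM was higher, from 5 to 26 counts. Of 13 measured ERK feedback and output genes 5 were lower and 0 higher (median -0.48, -0.82 to -0.26, percentile 0.40), including the transcription factor ETV1, 3.08-fold lower (2.75 to 3.46), and SPRY4, 2.53-fold lower (2.25 to 2.85). Of 10 measured NF-kB and inflammatory genes 7 were lower and 0 higher, with a median of -1.18 (-1.35 to -0.90) at percentile 0. TNFAIP3, an inhibitor of NF-kB, was 6.41-fold lower (5.40 to 7.69), and IL6 had 82 and 3 counts, 22.7-fold lower (8.68 to 130). As the ratio of summed CPM this list gave -0.53, below the 1.5-fold size.

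AP-1 and immediate early genes moved both ways, 5 higher and 4 lower of 13 measured (median -0.19, percentile 8.67). DUSP1 was 2.17-fold higher (1.88 to 2.5) and BTG2 also higher, while ATF3 was 4.70-fold lower (4.27 to 5.19) and MAFF 2.63-fold lower. Of 16 measured interferon-stimulated genes 2 were higher, IFIT3 and OAS3, and 2 lower, IFITM2 and IFI35, with a median of -0.21 at percentile 8.27.

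Of 30 G1/S and DNA replication genes 7 were higher and 0 lower, with a median log2 ratio of 0.35 (0.31 to 0.39) at percentile 100. GINS1, a subunit of the replicative helicase complex, was 1.69-fold higher (1.55 to 1.84). Of 27 measured G2/M and mitosis genes 2 were higher and 0 lower (median 0.24, percentile 99.2), ANLN by 1.61-fold and MKI67, a proliferation marker, by 1.51-fold. Among 13 D cyclins and CDK inhibitors 1 was higher, CDKN1C at 1.82-fold, and 3 lower, with a median of 0.09 at percentile 72.8. CDKN1A, the inhibitor p21, was 2.54-fold lower (1.98 to 3.31) and CCND2, which is also in the STAT5 list, 2.26-fold lower (2.09 to 2.45). Of 18 measured replication-dependent histone genes 2 were lower, HIST1H3B and HIST1H4H, and 0 higher (median -0.10, percentile 24.3).

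Of 22 genes of MYC and ribosome biogenesis 3 were higher and 0 lower (median 0.36, percentile 99.98), among them NOP16, 1.71-fold higher, and NOP56, 1.65-fold higher. MYC itself had a log2 ratio of -0.13 (-0.17 to -0.09). Of 40 cytosolic ribosomal protein genes 1, RPS28 at 1.93-fold on 66 and 123 counts, was higher, and the median of 0.08 (percentile 44.1) turned to -0.01 under scaling by total counts. Of 19 measured apoptosis regulators 5 were lower and 1 higher (median -0.17, percentile 5.02). BBC3, which encodes PUMA, was 1.99-fold lower (1.81 to 2.18) and BCL2 1.97-fold lower on 64 and 31 counts. BCL2L11, which encodes BIM, was 1.57-fold higher (1.41 to 1.76). Of 20 chromatin and DNA methylation enzymes 4 were higher and 0 lower (median 0.13, percentile 84.5), including UHRF1 at 1.94-fold and KAT2B at 1.81-fold.

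Of 20 glycolysis genes 2 were higher and 2 lower (median -0.05, percentile 7.73). The glucose transporter SLC2A1 was 2.45-fold higher (2.36 to 2.54) and its relative SLC2A3 2.56-fold lower (2.42 to 2.72). PFKFB4 was 1.63-fold higher and PFKM 1.65-fold lower. Of 12 measured hypoxia response genes 4 were lower and 0 higher (median -0.25, percentile 2.41), VEGFA by 2.39-fold (2.30 to 2.48) and ANKRD37 by 1.84-fold (1.18 to 2.99). Among 24 cholesterol genes only STARD4 was past 1.5-fold, 1.61-fold lower, with a median of -0.05 at percentile 6.41 that turned to 0.03 as the ratio of summed CPM. None of 30 nuclear-encoded respiratory chain genes passed 1.5-fold, with 0 higher and 0 lower, and their median of -0.00 at percentile 11.7 turned to 0.02 with the length trend removed. Of 13 mitochondrially encoded genes 3 were higher and 0 lower (median 0.42, 0.39 to 0.46, percentile 99.92), including ATP8 at 1.63-fold and ND5 at 1.62-fold. Genes of the mitochondrial chromosome took 4.12% of counts in DMSO (4.11% to 4.13%) and 4.90% with cabozantinib (4.89% to 4.91%).

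Of 21 genes of the actin cytoskeleton and adhesion 7 were lower and 2 higher (median -0.05, percentile 12.7). VIM, the intermediate filament vimentin, was 4.73-fold lower (4.49 to 5.0) and ANXA1 4.22-fold lower (4.10 to 4.35), from 879 to 208 CPM. By contrast, ITGA4 and S100A4 were 1.51-fold and 1.52-fold higher on fewer than 100 counts per library. Of 4 measured drug efflux transporters ABCB1 was 2.08-fold lower (1.46 to 3.03) and 0 were higher (median 0.01, percentile 43.1). That median turned negative under 4 alternatives, to -0.07 under scaling by total counts. The 1 measured metallothionein, MT2A, had a log2 ratio of 0.18 (-0.36 to 0.70), and with no filter on low counts the list median was -0.82. Of 10 reference genes 1, POLR2A at 1.51-fold, was higher and 0 were lower (median 0.11, percentile 63.7).

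The authors' deposited table gave a posterior probability of differential expression of 0.95 or more to 810 genes. Of these, 241 were higher and 569 lower with cabozantinib in the authors' deposited table. Of the genes called there, 208 of the higher and 499 of the lower also passed the 2-fold rule, and 0 went the opposite way. Another 42 genes called in the authors' deposited table were under 1 CPM, and 61 were measured but did not pass the 2-fold rule. Among genes with a mean of at least 10 CPM, log2 folds of the authors' deposited table and those computed here differed by at most 0.0094. Both folds follow the same counts, so their closeness and shared directions are no separate check of the calls. With 1 library per group, the posterior probability has no replicates behind it either.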

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

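The alternatives on GC content, totals without globins and mitochondrial genes, protein-coding genes and abundance were chosen after seeing the data. No list median of at least 1.5-fold and no named gene called at 1.5-fold changed direction under the alternatives run on it. For single genes this was fixed in advance and shows nothing on robustness. Their alternatives only rescaled slightly, filtered or shrank ratios of the same counts, and trends were not removed from them. Called genes that are not named were not checked one by one. Over the alternatives of scaling, filter, pseudocount, trend and abundance the ratio of lower to higher genes lay between 1.88 (mean of at least 10 CPM) and 2.92 (total counts, 284 higher and 829 lower). Fewer genes enter at 5 CPM or more (165 higher, 396 lower) and at a mean of at least 10 CPM (126 and 237), and a 1.5-fold threshold takes more (1022 and 1543). With no filter there were 467 and 1023. Of 28 counts of genes under alternatives 22 stayed within 1.5 times the reported one. Scaling by total counts shifted the median of all measured genes by -0.08 and gave medians of 1.65 for globins, 1.11 for heme, 0.99 for red cell membrane, -1.04 for STAT5, -1.45 for ATF4 and 0.83 for heat shock genes. Summed CPM, which weights abundant members, gave 1.52, 1.07, 0.79, -1.05, -1.13 and 0.75 in the same order. The upper quartile gave 1.72 for globins, totals without globins and mitochondrial genes 1.70 for globins and 0.88 for heat shock, the length trend 1.01 for red cell membrane, and a 5 CPM filter -1.21 for ATF4. Over all lists 362 medians under alternatives stayed within the counting interval and 77 left it, and of single genes 775 did and 33 left it. The filter alternatives leave the ratio of a single gene unchanged, so part of the 775 could not have moved. The erythroid regulator and the stem and progenitor medians crossed the 1.5-fold size under 4 alternatives each, and those of ERK, hypoxia, NF-kB and metallothionein genes under 1 each. The cause was not tested. No paired analysis was possible because each group holds 1 library, and no library could be left out. Depth limits genes near 1 CPM, which rest on about 25 counts.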

Other observations

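The gene pairs below, the scaling test of the excess of lower genes, the intron test and the 3 tests on the ATF4 genes were chosen after the results that prompted them were seen. The intron test was written before the microRNA values it uses were known. The remaining tests below were also written for patterns seen in the results, namely the excess of lower genes and the lower RN7SK, RN7SL1 and RN7SL2. These RNAs are in no gene list.

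The adaptor gene GAB1 had a log2 ratio of 1.39 (1.28 to 1.5), from 38.4 to 101 CPM, while GAB2, which couples BCR-ABL1 to downstream signalling, had one of -2.08 (-2.18 to -1.99), from 191 to 44.9 CPM. PKLR, the pyruvate kinase of red cells and liver, went from 102 to 291 CPM, a log2 ratio of 1.51 (1.45 to 1.58), while PKM, the common form, went from 399.7 to 296 CPM, a log2 ratio of -0.43 (-0.48 to -0.39), inside 1.5-fold. The glucose transporters SLC2A1 and SLC2A3, near equal in DMSO at 166 and 158 CPM, stood at 407 and 61.7 CPM with cabozantinib. Within the heat shock family HSPA1A had a log2 ratio of 2.44 and HSPA6, a strictly inducible member, one of -3.42 (-4.17 to -2.81), from 9.28 to 0.848 CPM.

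More genes were lower than higher. The lowest ratio of lower to higher genes under the other 3 scalings was 2.17. Each of them moved the log2 ratios down (median shifts of -0.0085, -0.0149 and -0.0843). None could therefore have removed this excess, and they decide nothing on scaling. Among genes with a mean of at least 10 CPM the ratio was 1.88, and from 30 to 100 CPM there were 39 higher and 80 lower genes. This argues against lost background reads as the whole of the excess. The excess followed abundance, however, and above 100 CPM there were 47 higher and 52 lower genes. The median log2 ratio rose from -0.215 below a mean of 2 CPM to 0.075 above 100 CPM. Lost background reads as a part of the excess therefore stay open. For genomic DNA in the DMSO library, 369 olfactory receptor genes had summed counts of 2210 and 1904, a log2 ratio of -0.158 (-0.247 to -0.069). The whole interval lies on the lower side, the direction such DNA would give, although the size is far from 2-fold. Whether a few transcribed receptor genes carry this sum was not tested. The sum therefore cannot decide on genomic DNA, which stays open. A response to the drug remains a hypothesis, with differences between the 2 cultures not tested.

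The short structured RNAs RN7SK, RN7SL1 and RN7SL2 were lower with cabozantinib, with log2 ratios of -2.23, -2.13 and -2.15, the last pair near-identical. A change of polymerase III transcripts as a class was predicted to give a median of at most -1 over at least 3 other such genes, and this was met at -1.77 over RPPH1 (-2.52), RMRP (-1.77) and BCYRN1 (-0.36, -0.71 to -0.01), so it stays open, although RNU1-2 (-2.27, on 27 and 5 counts) and SNORD3A (-1.25), polymerase II genes picked after their values were seen, were lower too. Weaker capture of RNA without a poly(A) tail was set before the test to be excluded if the upper end of the interval of the other small RNAs' median and the median of the replication-dependent histones were above -0.5, and both were, with 1.11 (0.89 to 1.14) over 83 small RNAs and -0.10 (-0.21 to -0.03) over 18 histone genes. The small RNA part is weaker than it looks, since many are snoRNA genes inside introns. Genes also entered at 1 CPM in either library. More did so only through cabozantinib (such as SNORD35A, 2 and 42 counts) than only through DMSO (such as SNORD102, 30 and 20 counts), which raises the median. RPPH1, RMRP, RNU1-2 and SNORD3A, which are transcribed on their own and lack a poly(A) tail, were lower, as weaker capture would give. The histone median of -0.10 shows no large loss over that list, but whether its RNAs lacked a tail here was not tested. It therefore cannot settle a loss across all RNA without a tail. Weaker capture of short structured RNAs of this kind stays open. The log2 ratio minus that of the host had a median of 0.81 (0.72 to 1.01) over 100 intronic snoRNA genes, 88 of them above their host, and of 0.53 (0.29 to 0.84, reaching below the 0.5 set in advance) over 14 intronic microRNA genes, 13 of them above it. Many of the snoRNA genes share a host, such as GAS5 or SNHG1, so they are not independent of each other. The intervals cover counting error of the intronic genes only, with the ratio of the host taken as fixed. All 189 intronic microRNA genes on the strand of their host, most with fewer than 20 counts, summed to 566 and 748 counts, a log2 ratio of 0.46 (0.30 to 0.62) with that of the hosts not taken off, where the median host of the 14 genes had 0.16. More unspliced RNA in the cabozantinib library is a weakly supported hypothesis.

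The lower ATF4 response genes kept a median log2 ratio of at most -1.37 after removing the length or GC trend. This argues against these trends as the whole cause. The median was at most -1.38 under the other 3 scalings, but each of these moved log2 ratios down, so they could not have raised it and decide nothing on scaling. Nutrient depletion or higher cell density in the DMSO culture may give the same pattern. The lists for hypoxia, glycolysis and cholesterol, of which each was predicted to be lower by 0.58 or more, had medians of -0.25, -0.05 (-0.11 to 0.00) and -0.05 (-0.10 to -0.02), with -0.60 for hypoxia by summed CPM, so that prediction was not met. It was written after the results were seen, and no value was set that would exclude depletion or density, so these medians cannot exclude them. A shortage of amino acids alone need not move those lists, and with 1 culture per group it cannot be told apart from the drug.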
